A study of Gossypium hirsutum with 24 samples.

How the data were processed

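The deposited processed file, a single table of 24132 probe sets and 24 arrays, was used. Per the labels, RNA was extracted from leaves by a modified CTAB method, biotin-labelled cRNA was hybridised to an Affymetrix cotton array, and the authors normalised the signals by RMA, for which the labels gave no version. The step from RMA output, which is usually in log2, back to a linear scale was not stated in the labels. The deposited values were linear intensities (array minima 1.74 to 2.10, maxima 12356 to 14854), so the log2 of each intensity was taken before any comparison, where the plan had assumed that the deposited values were already in log2. Nothing else was done to the values before modelling. Group membership came only from the labels, which named the pre-treatment, the inoculation and the day of each array and gave a completely randomised design with 3 replications. The labels gave the night temperature of normal plants as 20 °C in one place and that of the growth chamber as 22 °C in another.

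The 103 probe sets of the array maker's controls were set aside, and 24029 were tested, among them 52 reporter and 4 ribosomal RNA probe sets. A linear model with 8 group means was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3, with variances moderated by empirical Bayes. There were 12 contrasts: inoculated against mock in each kind of plant on each day, the difference of these effects between chilled and normal plants on each day, chilled against normal plants in mock and in inoculated plants on each day, and the difference of the inoculation effect between the days in each kind of plant. P-values were adjusted by the method of Benjamini and Hochberg within each contrast over the 24029 probe sets, and an adjusted p under 0.05 was called. All p-values beside small groups are these moderated p-values unless a permutation or an exact test is named. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

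Gene identities came from the supplied pairing of probe sets and genes. It gave 697 probe sets a single gene, 46 several and 23389 none, so that 520 genes could be named, 122 of them with more than 1 probe set. The locus tags were paired with symbols through a RefSeq gene table, and 246 genes had a readable name. No gene descriptions were at hand, so gene lists were composed from symbol patterns alone. Where a gene had several probe sets, the one with the highest mean over the 24 arrays stood for it. The numbers of other probe sets called in the same and in the opposite direction were kept. A gene was named for its size of change if its adjusted p was under 0.05, with all arrays of one group beyond all of the other (the latter not asked of interactions), and if it was among the 10 largest changes in either direction. From each list the members with the smallest adjusted p in each direction, up to 2, were also named, or a single member if none passed. For chilled against normal mock plants at 6 DAI, 1 of the 37 genes chosen by these rules had another probe set called in the opposite direction. In the other comparisons no chosen gene had one.

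Of 29 gene lists fixed before the data were examined, 15 had a member and 14 were empty. The NAC (6 genes), ethylene (9), class III peroxidase (11), cell wall loosening (7) and reference actin (5) lists had at least 5 genes and were tested with camera from limma, with the preset correlation of 0.01 between genes and adjustment over the 60 tests. Each was tested again with a correlation estimated from the data, and none of the 13 calls was kept in that form. Lists of fewer genes (WRKY, late embryogenesis, CBF, flavonoid, GST, catalase and superoxide dismutase, Lox1, CCR1, CelA1, E6) were counted only. Counts of list members were made over all probe sets and again adjusted over the list alone. Symbols do not prove function: cdn1, CCoAMOT2 and CSD2a/CSD2b matched no list pattern, and ACS1 and ACS3/ACS6 were in the ethylene list by name alone. A further 6 lists composed after the results were seen were tested over 72 tests and are used only in the last part.

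Array quality was described from control probe sets. Chilled and normal arrays, and inoculated and mock arrays, were compared by two-sided permutation tests on 12 and 12 arrays with 1e+05 resamples. Arrays were placed by the mean Pearson correlation of gene-centred log2 values with the arrays of each group. After the results were seen, the 95th percentile of the reporter probe sets on each array, without the brightest one, was taken as a level of detection. For each named change, arrays of the lower group below it were set to it to give a lower bound of the fold. Reporter calls in each comparison of chilled with normal plants were set against those of inoculated with mock normal plants on the same day by one-sided Fisher exact tests.

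Each comparison was repeated under alternatives chosen before the data were examined: a replicate-number block, a further quantile normalisation, equal array medians, only probe sets with a mean log2 intensity of at least 5 (13326), only the arrays of the groups compared, changes of at least 2-fold, an intensity trend with robust variances, 1 probe set per named gene, and each array left out in turn. A fit on 22 arrays, without the replicate 3 arrays of mock-inoculated normal and inoculated chilled plants at 6 DAI, was added after the results were seen.

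The fit was tested on simulated data with 24029 probe sets, of which 200 were changed 2-fold or 4-fold. Noise was normal and independent between probe sets, and only the inoculated chilled group at 3 DAI was changed. The shares below hold for such data and not for correlated probe sets or widespread changes. In the comparison of chilled plants at 3 DAI it found 90% of the 2-fold and 99% of the 4-fold changes, with 10 false among 199 calls. In the interaction at 3 DAI it found 65% and 96%, with 13 false among 174 calls. In the unchanged comparison of normal plants at 3 DAI it made 0 calls. Raw array images and sequences outside the processed file were not analysed here.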

Results

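Transcript levels were measured with Affymetrix microarrays in leaves of upland cotton (Gossypium hirsutum, variety Xinluzao13) from plants that carried 3 to 4 leaves. Some plants had been chilled at 16 °C by day and 12 °C by night for 3 days, and the others had stayed at 28 °C by day and 20 °C by night. Plants of both kinds were then inoculated with isolate A1 of Alternaria alternata, a fungus that causes leaf spot, or mock-inoculated with sterilised water. Leaves were sampled 3 and 6 days after inoculation (DAI). The 24 arrays formed 8 groups of 3, and 24029 probe sets were compared. The values were linear intensities with array medians from 41.8 to 46.7, and their log2 was used throughout. The number of arrays limited the precision of every comparison.

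A first principal component held 32.1% of the variance of the log2 values and a second held 28%. By correlation of gene-centred values, 22 of the 24 arrays lay nearest to the other arrays of their own group. Replicate 3 of the mock-inoculated normal plants at 6 DAI lay nearer to the mock-inoculated normal plants at 3 DAI (mean r 0.501) than to its own group (mean r 0.350). Replicate 3 of the inoculated chilled plants at 6 DAI lay nearer to the inoculated chilled plants at 3 DAI (mean r 0.477, against 0.394). These correlations are across genes, and genes are not independent replicates.

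**Figure D1:**
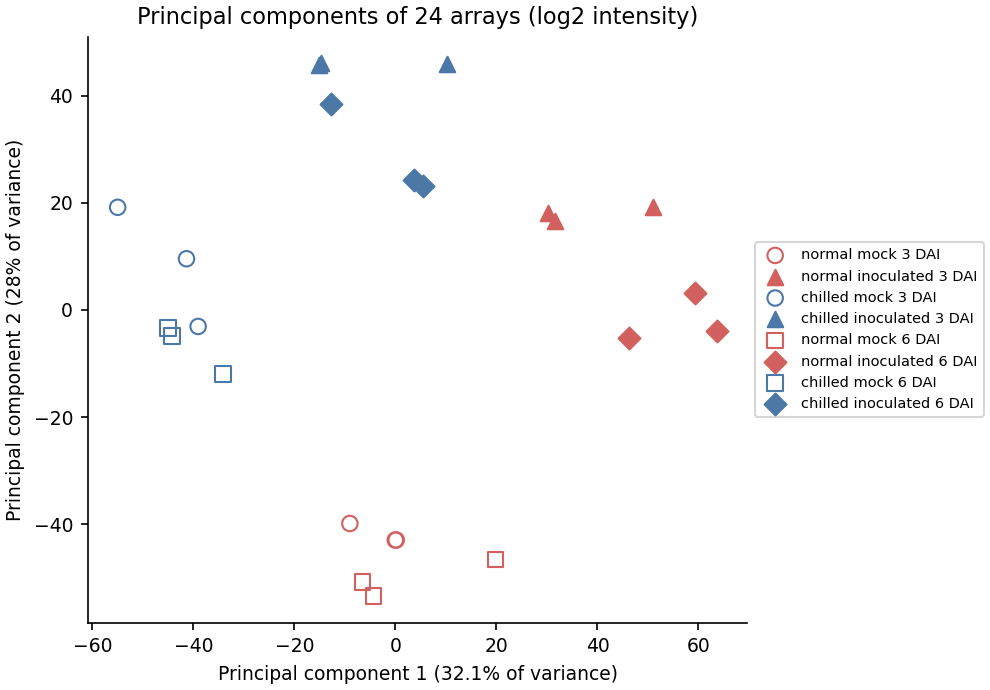
Scores of the 24 arrays on the first component (horizontal axis, 32.1% of the variance) and the second (vertical axis, 28%) of the log2 intensities, without units. Red marks stand for normal and blue marks for chilled plants, open marks for mock and filled marks for inoculated plants, and the mark's shape gives the day.

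Only 520 genes could be named, through the probe sets that were paired with a single gene, so the named genes cover a small part of the array. Gene levels below are means of log2 intensity with SD, n = 3 arrays per group, and changes are log2 fold changes with the standard error (SE) of the limma model. For each gene named for the size of its change between groups, all 3 arrays of one group lay beyond all 3 of the other, which chance gives for 10% of genes with no difference. Members named for their gene list were not held to this. Reporter probe sets, made for sequences of other organisms, marked the level at which an array could not be taken to detect a transcript. Their 95th percentile, without the brightest one, was 3.78 to 4.83 on the log2 scale per array. Where arrays of the lower group lay below it, a fold is given as at least the value against that level, and genes below it were kept in the counts. The p-values measure the spread between these arrays, and the labels, which give a completely randomised design with 3 replications, do not state whether the replications were separate plants.

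The comparison of inoculated with mock-inoculated normal plants at 3 DAI asked how unchilled leaves responded to the fungus. A strong rise was in cdn1 (LOC107903500), which encodes delta-cadinene synthase, the entry enzyme to cotton's gossypol-type phytoalexins. Its measured level went from 4.02 ± 0.96 to 9.05 ± 0.26 (log2 5.03, SE 0.40, adjusted p = 1.3e-08), a change of at least 24.1-fold, as 1 of the 3 mock arrays lay below the reporter level. The class III peroxidases pod7 (LOC107936187) and pod6 (LOC107908968), secreted haem enzymes, rose 30.9-fold and, with all 3 mock arrays below the reporter level, at least 17.8-fold (measured log2 4.95, SE 0.31, and 4.81, SE 0.37). CCoAMOT2 (LOC107945134), a caffeoyl-CoA O-methyltransferase of lignin monomer synthesis, rose 8.14-fold (log2 3.02, SE 0.17, adjusted p = 9.1e-11). The ethylene response factor ERF7 (LOC107941184) rose at least 5.23-fold (1 of 3 mock arrays below the reporter level), and the glutathione S-transferase GST at LOC107889738 rose 4.57-fold. The peroxidase pod3 (LOC107927057) fell from 7.95 ± 0.13 to 5.95 ± 0.51 (SE of the change 0.20, adjusted p = 3.7e-07).

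Of the 11 class III peroxidases measured in these plants at 3 DAI, 4 rose, 2 fell and 5 did not pass (5 rose and 2 fell when adjusted over the list alone). POX5 (LOC107914564) rose 5.55-fold and pod1 (LOC107945392) fell by 0.78 on the log2 scale. The list shifted upward in the camera test (adjusted p = 0.042; median log2 change 0.16, mean 1.06), and this was lost with the correlation taken from the data (adjusted p = 0.23 with an estimated correlation). It was also lost without replicate 1 or replicate 3 of the inoculated group (adjusted p = 0.078 and 0.053, with medians of 0.02 and 0.04). Other settings that lost it were only probe sets of a mean log2 of at least 5 (0.48, median 0.57), median centring (0.053) and 22 arrays (0.058). The setting of 22 arrays, added after the results were seen, leaves out both arrays lying nearer to another group. Of 6 NAC transcription factors, 4 rose and 2 did not pass, with the same counts adjusted over the list alone. NAC5/NAC8 (LOC107892421) rose by 0.90 and NAC2 (LOC107962533) by 0.41 (list adjusted p = 0.01, and adjusted p = 0.23 with an estimated correlation). Of 9 genes of the ethylene list, 3 rose, 1 fell and 5 did not pass (3 rose and 3 fell adjusted over the list alone), with median −0.02, mean 0.30 and camera upward (adjusted p = 0.45). This list was matched on names, and the symbol ACS1 (LOC107950760, up by 0.71) is also used for enzymes outside ethylene synthesis. Of 7 cell wall loosening genes, the expansin EXPA11A (LOC107885990) rose at least 2.08-fold, from mock arrays that all lay below the reporter level, and 6 did not pass, also adjusted over the list alone (list adjusted p = 0.45).

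Lists of fewer than 5 genes were not tested as groups. In normal plants at 3 DAI both late embryogenesis genes fell, Lea14-A (LOC107922715) by 0.58 and Lea5-D (LOC107916177) by 0.51, also adjusted over the list alone. Of 3 CBF genes, whose family acts in cold responses, CBF20/DREB1C (LOC107898106) rose by 1.08, CBF15/DBP2 (LOC107957738) rose by 0.52 and 1 did not pass, with the same counts adjusted over the list alone. WRKY15 (LOC107931629) rose by 0.62, while the other WRKY gene did not pass, also adjusted over the list alone. The lipoxygenase Lox1 (LOC107919998) rose by 0.78 (adjusted p = 0.0087, but 0.063 without replicate 2 of the inoculated group). E6 (LOC107913945), a protein of cotton fibre cells and thus a marker of another cell type, rose from below the reporter level on all 3 mock arrays (2.65 ± 0.18 to 4.28 ± 0.23, at least 1.24-fold, adjusted p = 0.0015). The second GST (LOC107948407) changed by −0.69, the iron superoxide dismutase FeSOD (LOC107894059) by −0.58 and the cinnamoyl-CoA reductase CCR1 (LOC107951749) by −0.62, all past the threshold. The calls of Lea5-D, CBF15/DBP2, CCR1, FeSOD and the second GST were each lost without 1 to 5 of the 6 single arrays, with adjusted p of up to 0.079, 0.06, 0.065, 0.077 and 0.2.

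In normal plants at 3 DAI, limma called 3748 probe sets (15.6% of those tested), 1813 higher and 1935 lower in inoculated leaves. At least 2-fold changes were found in 711 of the higher and 201 of the lower ones. Among the named genes 74 were higher and 44 lower. The side with more probe sets depended on the scaling, with 1934 higher and 1604 lower when each array's median was set equal. Without replicate 2 of the inoculated group the count was 2357.

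The comparison of inoculated with mock-inoculated normal plants at 6 DAI asked how the response stood later. Strong rises were again in pod7 (18.1-fold, log2 4.18, SE 0.31, adjusted p = 5.9e-09), pod6 (at least 7.83-fold, with 3.23 ± 0.22 measured in mock leaves, below the reporter level on all 3 arrays, and 6.92 ± 1.19 in inoculated leaves) and cdn1 (12.7-fold, log2 3.67, SE 0.40). ERF7 rose at least 5.66-fold (2 of 3 mock arrays below the reporter level), CCoAMOT2 5.5-fold and GST (LOC107889738) 4.82-fold. Several cell wall genes fell. The expansin EXPA3D (LOC107904848) went from 9.93 ± 0.66 to 7.51 ± 0.13 (log2 −2.42, SE 0.35, adjusted p = 5e-05), and the xyloglucan endotransglucosylase XTH/XTH1 (LOC107911611) changed by −1.96. A second gene of that family, XTH (LOC107886823), and PGIPL (LOC107926247), named as a polygalacturonase inhibitor-like gene, fell below the reporter level on all 3 inoculated arrays, at least 1.58-fold and 1.81-fold. The germin-like Glp1 (LOC107907099) fell at least 4.93-fold (1 of 3 inoculated arrays below that level).

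Of the 7 cell wall loosening genes, 4 fell and 3 did not pass in normal plants at 6 DAI, also adjusted over the list alone. Their median change was −1.55, and the camera test called the list lower (adjusted p = 0.01), which was lost in the second form of the test (adjusted p = 0.42 with an estimated correlation). NAC genes again rose in 4 of 6 cases, with 2 that did not pass, also adjusted over the list alone, led by NAC7 (LOC107909534), up by 1.25 (list adjusted p = 0.001, and adjusted p = 0.2 with an estimated correlation). Of the 9 ethylene genes, 4 rose and 5 did not pass (4 rose and 1 fell adjusted over the list alone), and the list was called higher (adjusted p = 0.04, and 0.21 with an estimated correlation). That call was lost without replicate 2 of the inoculated or replicate 3 of the mock group (adjusted p = 0.061 each), with only probe sets of a mean log2 of at least 5 (0.39), with 22 arrays (0.07) and with only the arrays of the groups compared (0.065). Of 11 peroxidases 3 rose, 3 fell and 5 did not pass, with the same counts adjusted over the list alone and a median of −0.02, a mean of 0.58 and an upward camera test (adjusted p = 0.42).

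All 4 flavonoid genes measured in normal plants at 6 DAI were called lower in inoculated leaves, also adjusted over the list alone. Of these, CHS3 (LOC107912380) lay below the reporter level on all 3 arrays of both groups, so its fall was not shown to be in a detected transcript. They included the chalcone synthase CHS6 (LOC107934821, −1.28, SE 0.33, adjusted p = 0.0093) and the dihydroflavonol reductase DFR (LOC107957957, −1.04, SE 0.31, adjusted p = 0.023). For both genes the arrays of the groups overlapped. For CHS6, 2 of the 3 inoculated arrays lay below the reporter level, so that its fall was at least 1.46-fold. The calls of CHS6 and DFR were lost without 3 and 4 of the 6 single arrays, with adjusted p of up to 0.076 and 0.15. Of 3 CBF genes 2 rose, with CBF20/DREB1C up by 1.09, and 1 did not pass (3 rose adjusted over the list alone). WRKY15 rose by 0.81, while Lea14-A fell by 0.54. E6 did not pass here (−0.55, adjusted p = 0.28), nor did Lox1 (0.16, adjusted p = 0.66). Of 5 actins used as reference genes, ACT4 (LOC107890338) fell by 0.40 and ACT11 (LOC107913713) by 0.33, also adjusted over the list alone, and 3 did not pass (list adjusted p = 0.17). The ACT11 call was lost with median centring, with a replicate block and without 5 of the 6 single arrays (adjusted p of up to 0.22), and the ACT4 call without replicate 2 of the mock group (0.069).

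In normal plants at 6 DAI, limma called 4359 probe sets (18.1%), 2060 higher and 2299 lower, with changes of at least 2-fold in 696 and 373 of them. Among the named genes 70 were higher and 81 lower. With only the arrays of the groups compared the count was 1939, with 1157 higher and 782 lower, and with each array's median set equal the split was 2286 higher and 1915 lower, so the side with more probe sets was not settled.

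The comparison of inoculated with mock-inoculated chilled plants at 3 DAI asked how leaves that had been chilled responded. The same peroxidases rose strongly, beside LOC107904021, whose product was not named (22.2-fold). pod7 rose from 6.11 ± 0.87 to 10.47 ± 0.29, a 20.6-fold change (log2 4.36, SE 0.31, adjusted p = 5.9e-09). pod6 rose at least 7.29-fold and POX5 at least 5.04-fold, with 3 and 1 of the 3 mock arrays below the reporter level. cdn1 rose 4.92-fold (log2 2.30, SE 0.40, adjusted p = 0.00061), CCoAMOT2 4.8-fold (log2 2.26, SE 0.17) and ERF7 3.84-fold. GLU (LOC107932771) rose 5.23-fold and GST (LOC107889738) 2.45-fold. The beta-tubulin BTub1/BTub2 (LOC107962977) fell by 1.95 (SE 0.37, adjusted p = 0.0013), while pod3 and ACS3/ACS6 (LOC107947061) fell at least 3.01-fold and 2.17-fold, with 1 of 3 inoculated arrays below the reporter level each.

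Of the 11 peroxidases, 4 rose, 1 fell and 6 did not pass in chilled plants at 3 DAI (4 rose and 2 fell adjusted over the list alone). As a list they missed the threshold (adjusted p = 0.067, median 0.38). They passed it without replicate 1 of the inoculated or replicate 3 of the mock group (0.015 and 0.012, with medians of 0.62 and 0.63). They also passed with a further quantile normalisation (0.048). Of 6 NAC genes only NAC5/NAC8 rose, by 1.03, and 5 did not pass (2 rose adjusted over the list alone; list adjusted p = 0.15). The ethylene list had 2 genes that rose, 3 that fell and 4 that did not pass, with the same counts adjusted over the list alone. Its median was 0.04, its mean −0.03 and the camera test downward (adjusted p = 0.69). None of the 7 cell wall loosening genes and none of the 4 flavonoid genes passed, also adjusted over the list alone (cell wall list adjusted p = 0.5). Lea14-A fell by 0.81 and Lea5-D by 0.86. E6 rose at least 1.93-fold (measured from 3.41 ± 1.06, with 2 of 3 mock arrays below the reporter level, to 5.16 ± 0.08, adjusted p = 0.0012), and CBF20/DREB1C rose by 0.89 (adjusted p = 0.0011). With only the arrays of the groups compared, the calls of E6 and CBF20/DREB1C were lost (adjusted p = 0.059 and 0.064). Lox1 (−0.18, adjusted p = 0.66), CCR1 (−0.35, 0.22) and DFR (−0.81, 0.11) did not pass.

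In chilled plants at 3 DAI, limma called 2613 probe sets (10.9%), 1511 higher and 1102 lower, with changes of at least 2-fold in 496 and 208. Among the named genes 68 were higher and 42 lower. The count was 1503 without replicate 1 of the inoculated group and 1438 with only the arrays of the groups compared.

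The comparison of inoculated with mock-inoculated chilled plants at 6 DAI asked the same later. The largest rises among the named genes were in cdn1, from 5.79 ± 0.12 to 8.65 ± 0.11 (7.28-fold, log2 2.86, SE 0.40, adjusted p = 6.6e-05), and pod7 (6.52-fold, log2 2.70). CCoAMOT2 rose 4.88-fold, ERF7 at least 4.41-fold (1 of 3 mock arrays below the reporter level), CBF20/DREB1C 2.9-fold and GST (LOC107889738) 2.79-fold. The peroxidase pod3 fell by 1.52, and pod5 (LOC107922335) fell below the reporter level on all 3 inoculated arrays, at least 1.92-fold. Lea5-D fell by 1.06 (SE 0.15, adjusted p = 7.1e-05) and Lea14-A by 0.89. pod6, so strongly raised at 3 DAI, did not pass (0.72, adjusted p = 0.25).

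Of 6 NAC genes, 3 rose and 3 did not pass in chilled plants at 6 DAI (4 rose adjusted over the list alone), with NAC5/NAC8 up 2.07-fold and NAC7 1.68-fold. The list was called higher (adjusted p = 0.00031), which did not hold in the second form of the test (adjusted p = 0.2 with an estimated correlation). Of 3 CBF genes 2 rose and 1 did not pass, also adjusted over the list alone, with CBF15/DBP2 up by 0.96. The ethylene list had 4 genes that rose, among them ERF7 and ACS1 (0.87), 3 that fell and 2 that did not pass, with the same counts adjusted over the list alone (list adjusted p = 0.34). The calls of its falling members ERF8 (LOC107922990, −0.88) and ACS3/ACS6 (measured −0.76) were lost without 2 and 4 of the 6 single arrays, with adjusted p of up to 0.061 and 0.13. ACS3/ACS6 lay below the reporter level on 2 of the 3 inoculated arrays, so that its fall was at least 1.12-fold. Of 11 peroxidases 2 rose, 3 fell and 6 did not pass (2 rose and 4 fell adjusted over the list alone), with median −0.21, mean 0.02 and a downward camera test (adjusted p = 0.56). No cell wall loosening gene and no flavonoid gene passed, also adjusted over the list alone (cell wall list adjusted p = 0.34), and E6 did not pass (0.28, adjusted p = 0.68).

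In chilled plants at 6 DAI, limma called 2599 probe sets (10.8%), 1293 higher and 1306 lower, with changes of at least 2-fold in 405 and 160. Among the named genes 46 were higher and 49 lower. With each array's median set equal, the split was 1604 higher and 841 lower. The count was 1589 and 1702 without replicates 1 and 2 of the inoculated group, and 1624 and 1443 without replicates 2 and 3 of the mock group.

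**Figure D2:**
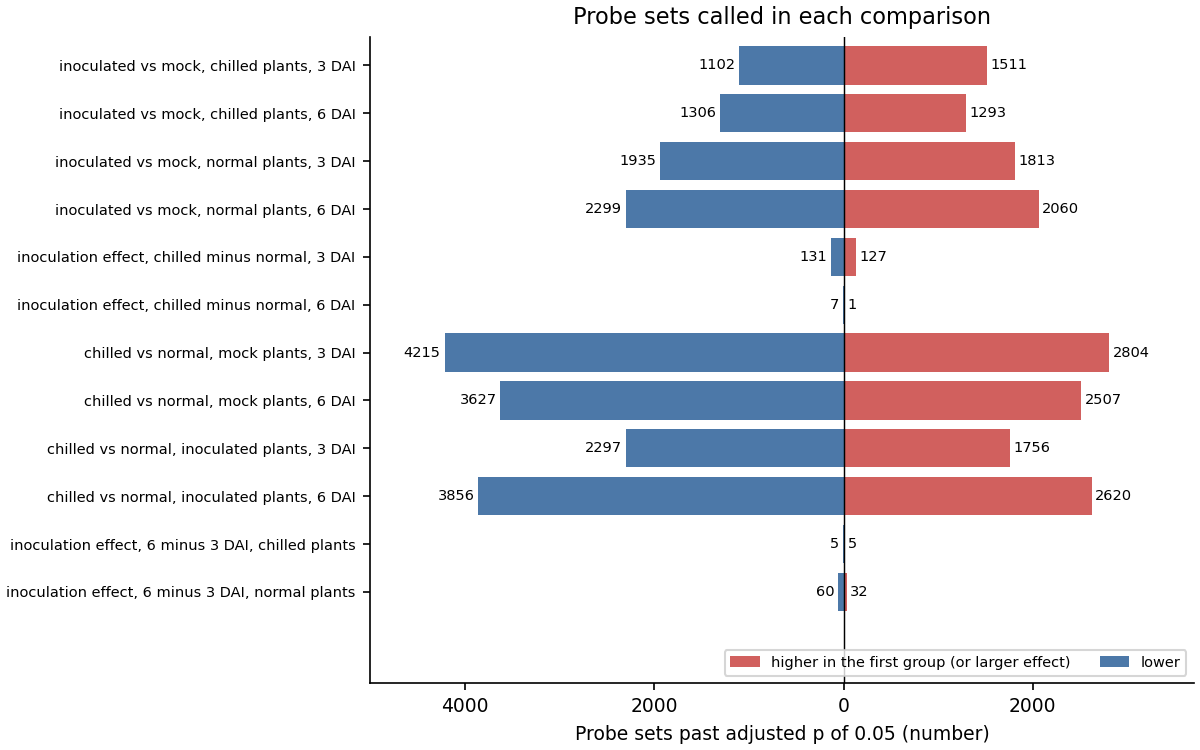
Probe sets called by limma at an adjusted p under 0.05 in each comparison (horizontal axis, number of probe sets), with those higher in the group named first, or with the larger effect, in red to the right and the lower ones in blue to the left. The comparisons of chilled with normal plants gave 4053 to 7019 calls and those of inoculated with mock plants 2599 to 4359.

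**Figure D3:**
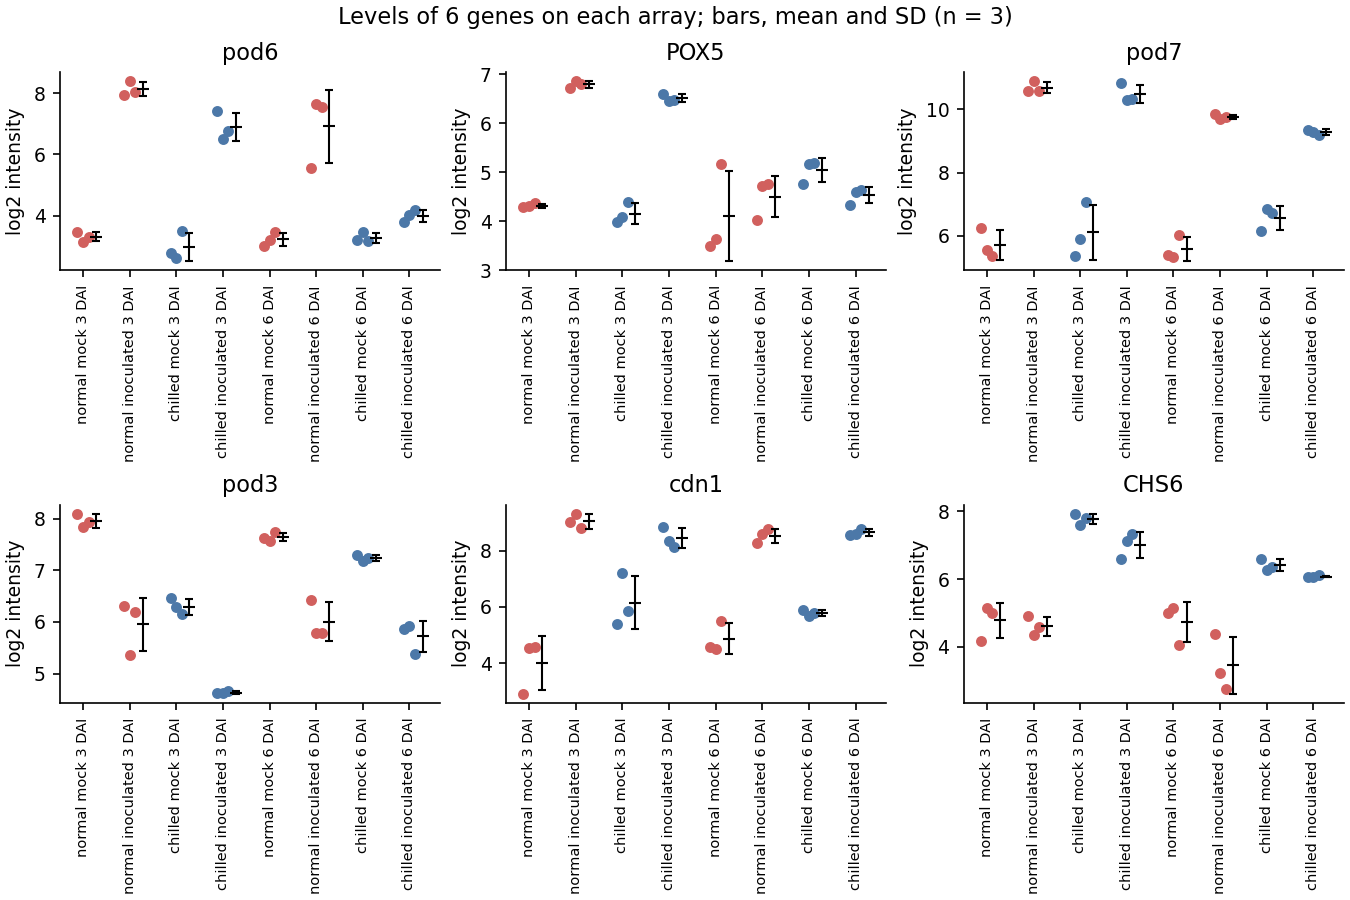
Log2 intensity (vertical axis) of pod6, POX5, pod7, pod3, cdn1 and CHS6 on each of the 24 arrays by group (horizontal axis), with normal plants in red and chilled plants in blue, and bars for the mean and SD of 3 arrays. pod7 and cdn1 lie higher in every inoculated group than in its mock group, pod3 lies lower, and CHS6 lies higher in every chilled group.

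Chilled and normal plants shared much of the response to the fungus. Both called 25 named genes higher on both days, among them cdn1, pod7, pod10 (LOC107914313), CCoAMOT2, ERF7, GST (LOC107889738), GLU, NAC5/NAC8, WRKY15, ACS1 and CBF20/DREB1C. Another 9 were called lower in all 4 comparisons, including pod3, Lea14-A and UGD2 (LOC107887357), a UDP-glucose dehydrogenase by its symbol. Over all probe sets, 610 were called higher and 178 lower in all 4 comparisons. At 3 DAI, 955 probe sets were called higher and 423 lower in both kinds of plant, where independent lists would share 114 and 88.7, and 19 were called in opposite directions. At 6 DAI, 949 were called higher and 674 lower in both, where independent lists would share 110.8 and 125, and 6 were opposite. The shared count at 6 DAI was 1623, with 1101 higher and 453 lower when each array's median was set equal, and it was 1044 without replicate 3 of the chilled mock group. Across probe sets, which are not independent, the log2 changes of chilled and normal plants had r = 0.699 (rho = 0.445) at 3 DAI and r = 0.774 (rho = 0.588) at 6 DAI.

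The difference between the responses was tested directly as an interaction, which asked whether chilling altered the response to the fungus. At 3 DAI the rise of cdn1 was smaller in chilled than in normal plants, by 2.74 on the log2 scale (SE 0.57, adjusted p = 0.024), with 2.30 in chilled and 5.03 in normal leaves. The rise of GST (LOC107889738) was smaller by 0.90 (SE 0.21, adjusted p = 0.038). In both genes the chilled mock leaves already stood higher than the normal ones (cdn1 6.14 ± 0.95 against 4.02 ± 0.96, GST 10.80 ± 0.26 against 9.80 ± 0.27), while the inoculated leaves did not differ past the threshold (−0.61, adjusted p = 0.33, and 0.10, adjusted p = 0.71). The ACC oxidase ACO1 at LOC107954048, an enzyme of ethylene synthesis, had an effect of −0.30 in chilled and 1.12 in normal leaves (difference −1.41, SE 0.34, adjusted p = 0.049). Rac9 (LOC107960222), a small GTPase, had 0.69 in chilled and −0.87 in normal leaves (difference 1.56, SE 0.34, adjusted p = 0.031). GRPL1/GRPL2/rgp1 (LOC107953490) fell by 0.75 in chilled leaves and did not pass in normal ones (0.37), with a difference of −1.11 (SE 0.19, adjusted p = 0.0084). LOC107946138 had the largest difference among the named genes (3.97, SE 0.83, adjusted p = 0.024), with 1.79 in chilled and −2.18 in normal leaves. Its mock leaves already differed (4.51 ± 0.59 in chilled, with 1 of 3 arrays below the reporter level, against 8.68 ± 0.20 in normal plants), and its inoculated leaves did not differ past the threshold (−0.21, adjusted p = 0.85). Of these 6 genes, GRPL1/GRPL2/rgp1 alone kept its call in each of the 12 fits that left out 1 array. The calls were lost in 5 such fits for cdn1 (adjusted p of up to 0.075), 6 for LOC107946138 (0.061), 8 for Rac9 (0.095), 8 for GST (0.12) and 11 for ACO1 (0.15). For cdn1, 1 of the 3 normal mock arrays lay below the reporter level. With only the arrays of the groups compared, cdn1 (0.086) and GST (0.093) were also lost, as was ACO1 with median centring (0.051).

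At 6 DAI the interaction called the peroxidase pod6 among the named genes. Its rise was smaller in chilled than in normal plants (0.72 against 3.69, difference −2.97, SE 0.53, adjusted p = 0.045), but all mock arrays and 2 of the 3 inoculated chilled arrays lay below the reporter level, so the size of the difference is not established. LOC107939902 was also called (difference −1.77, adjusted p = 0.042). Both calls were lost in most fits that left out 1 array (10 and 9 of 12, adjusted p of up to 0.18 and 0.13) and with a replicate block. The peroxidase list was shifted downward in this interaction, with 1 of 11 genes lower (3 lower adjusted over the list alone, median −0.44, adjusted p = 0.012, and adjusted p = 0.2 with an estimated correlation). With only probe sets of a mean log2 of at least 5 this was lost (adjusted p = 0.39). The cell wall loosening list was shifted upward with 0 of 7 genes past the threshold over all probe sets in limma (2 higher adjusted over the list alone, median 0.82, adjusted p = 0.013, and 0.44 with an estimated correlation). That shift was lost without replicate 3 of the inoculated chilled group (0.098), without replicate 1 of the chilled mock group (0.1) and with 22 arrays (0.059). The NAC and ethylene lists did not pass in either interaction (adjusted p = 0.25 and 0.085 at 3 DAI, 0.5 and 0.07 at 6 DAI). The ethylene list did pass at 6 DAI without replicate 3 of the inoculated chilled group (0.012, median −0.41 against −0.24), with 22 arrays (0.013) and with a further quantile normalisation (0.048), and at 3 DAI with 22 arrays (0.042). Of their genes, ACO1 passed at 3 DAI over all probe sets. Adjusted over the list alone, 2 NAC genes were lower, and 1 ethylene gene was higher and 2 lower, at 3 DAI, and none passed at 6 DAI.

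Limma called 258 probe sets for the interaction at 3 DAI, 127 higher and 131 lower. This split was not stable, with 93 higher and 138 lower when each array's median was set equal, and 247 higher and 149 lower among probe sets of a mean log2 of at least 5. Of the 258, 58 rose and 81 fell in normal plants without a call in chilled ones, 31 rose and 29 fell in chilled plants without a call in normal ones, and 37 rose in both, 34 of them less in chilled plants. At 6 DAI it called 8, 1 higher and 7 lower, with 2288 probe sets at an unadjusted p under 0.05. Leaving out single arrays moved the first count from 90, without replicate 2 of the inoculated chilled group, to 449, without replicate 1 of the chilled mock group. It moved the second from 0, without any of 7 arrays, to 572, without replicate 3 of the normal mock group, whose place among the arrays is given above.

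**Figure D4:**
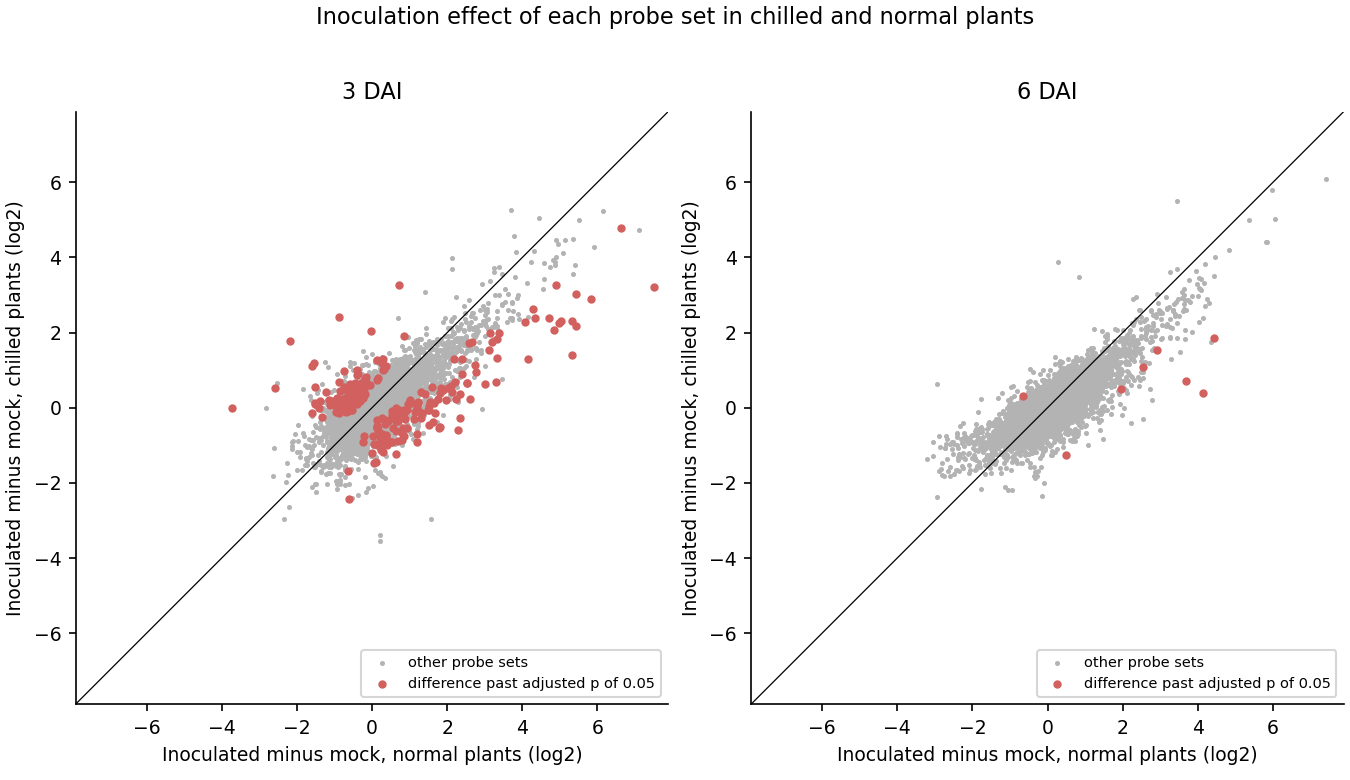
Log2 fold change of inoculated over mock plants of each probe set in normal plants (horizontal axis) and in chilled plants (vertical axis), at 3 and at 6 DAI, with equal effects on the line. Red points are the 258 and 8 probe sets called for the interaction and grey points the others, each from means of 3 arrays per group.

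The comparison of chilled with normal plants without the fungus asked what remained of the chilling at 3 DAI. The flavonoid gene CHS6 was at 7.78 ± 0.16 against 4.78 ± 0.52 (at least 7.9-fold, with 1 of 3 normal arrays below the reporter level, SE of the log2 change 0.33, adjusted p = 3.1e-06), DFR was 3.12-fold higher (log2 1.64, SE 0.31) and the chalcone synthase CHS2 (LOC107927759) 2.55-fold higher. Of the 4 flavonoid genes, 3 were higher and 1 did not pass (4 were higher adjusted over the list alone), although for CHS2 only 1 of its 3 other probe sets was called. CHS3, also of this list, lay below the reporter level on 2 of 3 chilled and all 3 normal arrays. CCoAMOT2 was 3.56-fold, cdn1 at least 3.22-fold and the calcium sensor CBL1 (LOC107912199) at least 2.37-fold higher, with 1 and 3 of the 3 normal arrays below the reporter level for the last pair. The sucrose synthase SusA1 (LOC107910106) was at 4.03 ± 0.26 against 6.80 ± 0.31 (log2 −2.77, SE 0.27, adjusted p = 5.9e-07), at least 6.32-fold lower with 2 of 3 chilled arrays below the reporter level. The copper/zinc superoxide dismutase CSD2a/CSD2b (LOC107889076) was at 7.53 ± 0.58 against 10.19 ± 0.12 (log2 −2.65, SE 0.21), and pod3 was also lower (−1.66).

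At 6 DAI in mock plants, CHS6 was 3.2-fold higher in chilled leaves (log2 1.68, SE 0.33, adjusted p = 0.0011). The dehydroascorbate reductase DHAR1 (LOC107959887) was 2.73-fold and the S-adenosylmethionine synthetase MAT/SAMS (LOC107910531) 2.64-fold higher. SusA1 (−2.89, SE 0.27, adjusted p = 7e-07) and CSD2a/CSD2b (−2.10) were again lower. All 3 CBF genes were lower in leaves that had been chilled, also adjusted over the list alone, with CBF15/DBP2 at −0.86 and CBF20/DREB1C at −0.81. At 3 DAI none of the 3 had passed in limma over all probe sets or over the list alone (CBF20/DREB1C −0.40, adjusted p = 0.079). NAC7 was lower by 1.02 (adjusted p = 5.4e-05). Of the flavonoid genes, 1 passed and 3 did not, also adjusted over the list alone.

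The lists with a test did not pass in these mock comparisons. Of the 6 NAC genes, 2 were higher and 2 lower at 3 DAI and 3 were lower at 6 DAI, with the same counts adjusted over the list alone (list adjusted p = 0.97 and 0.17). At 3 DAI the NAC median was −0.16 and the mean −0.12 with the camera test upward. Of the 9 ethylene genes, 4 were higher and 1 lower at 3 DAI, also adjusted over the list alone, and 1 was lower at 6 DAI (0 adjusted over the list alone; list adjusted p = 0.27 and 0.77). The ACO1 copies differed, with LOC107905899 at −1.28 and LOC107954048 at 1.06 at 3 DAI. Of the 11 peroxidases, 1 was higher and 1 lower at 3 DAI and 3 were higher at 6 DAI, with the same counts adjusted over the list alone (list adjusted p = 0.97 and 0.15). The peroxidase median at 3 DAI was −0.13 and the mean −0.10 with the camera test upward. Of the cell wall loosening genes, 2 were higher and 1 lower at 3 DAI, and none passed at 6 DAI, with the same counts adjusted over the list alone. For this list the camera adjusted p was 0.57 and 0.27, and at 3 DAI the median was −0.05 and the mean −0.02 with the test upward. ACT4 and ACT11 were lower at 6 DAI (−0.49 and −0.58), the other 3 actins did not pass, also adjusted over the list alone, and none passed at 3 DAI (list adjusted p = 0.085 and 0.49).

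In mock plants limma called 7019 probe sets between chilled and normal leaves at 3 DAI (29.2%), 2804 higher and 4215 lower, and 6134 at 6 DAI (25.5%), 2507 higher and 3627 lower. With each array's median set equal, the splits were 4074 higher and 2830 lower at 3 DAI and 3057 higher and 2921 lower at 6 DAI, so the side with more probe sets depended on the scaling. Of the named genes, 110 were higher and 64 lower at 3 DAI, and 89 were higher and 56 lower at 6 DAI. With only the arrays of the groups compared the counts were 4315 and 3580. On both days 3364 probe sets were called in the same direction and 45 in opposite directions.

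In inoculated plants, chilled leaves at 3 DAI again had higher CHS6 (7.01 ± 0.38 against 4.61 ± 0.28, 5.29-fold, log2 2.40, adjusted p = 8.1e-05) and lower CSD2a/CSD2b (−2.25, SE 0.21) and SusA1 (at least 3.43-fold, with 2 of 3 chilled arrays below the reporter level). Rac9 was 2.87-fold higher. Lox1 was lower by 1.21 (SE 0.19, adjusted p = 0.00036), NAC7 by 1.08 and Lea5-D by 0.79, and pod3 was at least 2.37-fold lower, with 1 of 3 chilled arrays below the reporter level. At 6 DAI, CHS6 was at least 3.7-fold higher (2 of 3 normal arrays below the reporter level, measured log2 2.62, SE 0.33, adjusted p = 1.4e-05) and DFR 2.67-fold higher. The expansin EXPA3D was at 10.05 ± 0.45 in chilled and 7.51 ± 0.13 in normal leaves (5.79-fold). PGIPL and XTH (LOC107886823) were also called higher, but lay below the reporter level on all 3 normal and 2 of the 3 chilled arrays. The peroxidase pod6 (adjusted p = 1.6e-05) was at least 5.43-fold and SusA1 at least 5.76-fold lower, each with 2 of 3 chilled arrays below the reporter level. CSD2a/CSD2b stood at −2.04, NAC7 at −1.53 and Lea5-D at −1.02. The fibre marker E6 was called with these cell wall genes, at 3.47 ± 0.08 in chilled and 1.71 ± 0.29 in normal leaves (adjusted p = 0.00062), but all 6 arrays lay below the reporter level, so no fold is given.

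Of the 7 cell wall loosening genes, 5 were higher in chilled inoculated leaves at 6 DAI and 2 did not pass, also adjusted over the list alone. The list had a median of 1.42 (adjusted p = 0.0067, and 0.38 with an estimated correlation). At 3 DAI none of the 7 passed over all probe sets or adjusted over the list alone (list adjusted p = 0.69). All 4 flavonoid genes were called higher at 6 DAI, also adjusted over the list alone, and 1 of 4 at 3 DAI (2 adjusted over the list alone). CHS3, among the 4, lay below the reporter level on all 3 arrays of each of these groups. Of the 6 NAC genes 1 was lower at each time (1 and 3 adjusted over the list alone; list adjusted p = 0.45 and 0.085), and the list passed at 6 DAI with a further quantile normalisation (0.048) and with 22 arrays (0.042). Of the 9 ethylene genes 1 was higher at 3 DAI and 2 lower at 6 DAI, also adjusted over the list alone (list adjusted p = 0.69 and 0.34). Of the 11 peroxidases 1 was higher and 2 lower at 3 DAI and 2 were higher and 2 lower at 6 DAI, also adjusted over the list alone (list adjusted p = 0.53 and 0.74). The cinnamoyl-CoA reductase CCR1 was higher on both days (0.82 and 0.95), and the cellulose synthase CelA1/CesA1 (LOC107909647) was higher at 3 DAI (1.11, adjusted p = 0.0061) and did not pass at 6 DAI (0.63, 0.076). The catalase CAT2 (LOC107943729) was higher by 0.39 at 6 DAI. Of the 5 actins, 1 was lower at 3 DAI and 3 at 6 DAI, also adjusted over the list alone (list adjusted p = 0.45 and 0.26), but the calls of ACT11 and ACT10/ACT12 (LOC107911663) at 6 DAI were lost without 4 of the 6 single arrays each (adjusted p of up to 0.063 and 0.11), and ACT10/ACT12 lay below the reporter level on all 6 arrays.

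In inoculated plants limma called 4053 probe sets at 3 DAI (16.9%), 1756 higher and 2297 lower in chilled leaves, and 6476 at 6 DAI (27%), 2620 higher and 3856 lower. With each array's median set equal the splits were 2501 higher and 1584 lower, and 3369 higher and 2732 lower. On both days 2926 probe sets were called in the same direction and 3 in opposite directions. The count at 3 DAI was 2056 and 2632 without replicates 2 and 3 of the chilled group, and 2288 and 2619 without replicates 2 and 3 of the normal group.

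Control probe sets also differed between chilled and normal arrays. The hybridisation controls, bacterial transcripts added to each sample, had a mean log2 intensity of 9.40 ± 0.18 on the 12 chilled and 10.24 ± 0.08 on the 12 normal arrays. The difference of −0.849 had a two-sided permutation p = 1e-05, the smallest that the resamples could give, and the ranges did not overlap. Between inoculated and mock arrays the same controls differed by −0.048 (permutation p = 0.79). The signal of the 3' end of actin over its 5' end, a sign of RNA quality, was 3.64 on chilled and 4.19 on normal arrays on the log2 scale (difference −0.543, permutation p = 5e-05). The lower value on chilled arrays means relatively more 5' signal. The corresponding ubiquitin difference was −0.502 (permutation p = 0.0049). For inoculated against mock arrays these differed by 0.047 (permutation p = 0.76) and 0.251 (0.19). Every flavonoid, SusA1, CSD2a/CSD2b and CBF difference between chilled and normal plants given above was measured beside this difference in controls.

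**Figure D5:**
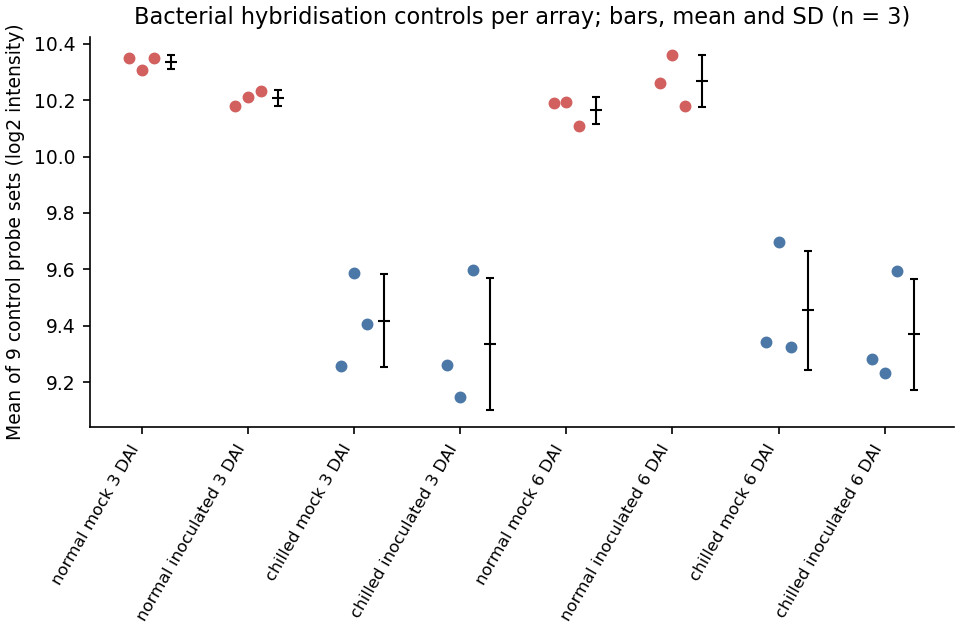
Mean log2 intensity of the hybridisation control probe sets (vertical axis) by group (horizontal axis), with points for single arrays and bars for the mean and SD of 3 arrays. The 12 chilled arrays (blue) lie between 9.15 and 9.70 and the 12 normal arrays (red) between 10.11 and 10.36.

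The change of the inoculation effect from 3 to 6 DAI was tested within each kind of plant. In chilled plants the effect on pod6 was smaller at 6 DAI by 3.20 on the log2 scale (3.92 at 3 DAI against 0.72, SE 0.53, adjusted p = 0.025) and that on POX5 by 2.86 (2.35 against −0.51, SE 0.40, adjusted p = 0.0039). In normal plants POX5 also had a smaller effect at 6 DAI (2.47 against 0.40, difference −2.07, SE 0.40, adjusted p = 0.03). There the expansin EXPA3D had 0.02 at 3 DAI and −2.42 at 6 DAI (difference −2.44, adjusted p = 0.037), and the fibre marker E6 had 1.63 and −0.55 (difference −2.19, adjusted p = 0.042). The alpha-tubulin ATub3/TUA6/TubA1 (LOC107886968) had 0.18 and −1.71 (difference −1.89), and the fasciclin-like FLA13 (LOC107911922) 1.57 and −0.08 (difference −1.65). In these comparisons the mock arrays of pod6, E6 and FLA13, the inoculated arrays of E6 and FLA13 at 6 DAI and 2 of 3 inoculated arrays of pod6 at 6 DAI lay below the reporter level, so these differences are measured against values not shown to be detected. For POX5 this held for 1 of 3 mock arrays at 3 DAI and 2 of 3 inoculated arrays at 6 DAI in chilled plants, and for 2 of 3 mock and 1 of 3 inoculated arrays at 6 DAI in normal plants. The call of POX5 in chilled plants was kept in all 12 fits that left out 1 array. That of pod6 was lost in 8 (adjusted p of up to 0.11), and in normal plants those of EXPA3D, E6, POX5, ATub3/TUA6/TubA1 and FLA13 were lost in 9, 10, 8, 9 and 9 (up to 0.13, 0.14, 0.086, 0.13 and 0.13).

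The 11 peroxidases shifted downward between the days in chilled plants, with 2 lower and 9 that did not pass (3 lower adjusted over the list alone, median −0.49). The camera test gave adjusted p = 0.00031, and adjusted p = 0.084 with an estimated correlation. With only probe sets of a mean log2 of at least 5 the shift was lost (median −0.05, adjusted p = 0.66). In normal plants 1 was lower and 10 did not pass, also adjusted over the list alone (adjusted p = 0.07). That list passed without replicate 2 of the inoculated group at 3 DAI (0.038) or at 6 DAI (0.032) and with a further quantile normalisation (0.048). The 7 cell wall loosening genes shifted downward in normal plants, with 1 lower and 6 that did not pass (3 lower adjusted over the list alone, median −1.85; adjusted p = 2e-06, and 0.2 with an estimated correlation). In chilled plants none passed over all probe sets or adjusted over the list alone (median −0.92, list adjusted p = 0.07), and the list passed without any of 4 single arrays (adjusted p from 0.0096 to 0.025), with a further quantile normalisation (0.048), with median centring (0.044) and with 22 arrays (0.018). The NAC and ethylene lists shifted upward in chilled plants with 0 genes past the threshold over all probe sets (2 and 1 higher adjusted over the list alone). Their adjusted p was 0.039 and 0.042, and 0.28 and 0.21 with an estimated correlation. The NAC shift was lost without 4 single arrays (adjusted p of up to 0.083) and the ethylene shift without 6 (up to 0.17), and both with 22 arrays (0.1 and 0.094). The NAC shift was also lost with only the arrays of the groups compared (0.065), and the ethylene shift with median centring (0.051) and with only probe sets of a mean log2 of at least 5 (0.39). In normal plants neither passed (adjusted p = 0.17 and 0.07), and the ethylene list passed without replicate 1 of the inoculated group at 6 DAI (0.039).

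Limma called 10 probe sets for the change between the days in chilled plants, 5 higher and 5 lower, with 2244 at an unadjusted p under 0.05, and 92 in normal plants, 32 higher and 60 lower. Leaving out single arrays moved these counts from 4 to 324 and from 14 to 1119. The highest values came without replicate 3 of the chilled mock group at 3 DAI and without replicate 3 of the normal mock group at 6 DAI. In chilled plants 1172 probe sets were called in the same direction on both days and 5 in opposite directions, and in normal plants 2172 and 14.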

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

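The tests of reporter probe sets, of exchanged labels and of RNA quality below were chosen only after results were seen, and the other tests were chosen before the data were examined.

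Chilled and normal arrays differed at more probe sets in mock plants (7019 and 6134) and in inoculated plants at 6 DAI (6476) than inoculated and mock arrays did (2599 to 4359), while the count in inoculated plants at 3 DAI (4053) was above the inoculation counts of that day (2613 and 3748) and below that of normal plants at 6 DAI, and for changes of at least 2-fold the ranges were alike (561 to 1018 against 565 to 1069). With only the arrays of the groups compared, the count in mock plants at 6 DAI was below that for inoculation of normal plants at 3 DAI. If differently processed batches that each held both days were the whole cause, the difference would be alike on both days. Its change between the days in mock plants was called at 373 probe sets (125 to 1395 with 1 array left out), which argued against such batches. Batches that also differed by day could give such a change, so the test cannot decide on them. The mock groups also hold the normal arrays whose labels may be exchanged. A batch may still be part of the cause: the hybridisation controls differed by −0.849 on the log2 scale, and reporter probe sets were called at 9 of 52 in mock plants at 3 DAI, against 1 of 52 for inoculation (one-sided Fisher exact p = 0.0079). In the other chilled against normal comparisons they were called at 3, 1 and 4 of 52 (exact p = 0.12, 0.75 and 0.059), and without a bright reporter that was called in all 4 (mean log2 13.51) the counts were 8, 2, 0 and 3 of 51 (exact p = 0.016, 0.25, 1 and 0.12). These exact tests count the same reporters in 2 contrasts, which share normal arrays, as separate samples. The cut on the unadjusted p was also looser in contrasts with more calls. The exact p thus does not measure a batch, and it was low in 1 of 4 comparisons, picked after all were seen. Of the array maker's 103 control probe sets, 44 and 49 were called in mock and 41 and 45 in inoculated plants at 3 and 6 DAI. For inoculation, 6 were called in normal plants on each day and 0 in chilled plants. The 103 control probe sets include some for cotton's own actin and ubiquitin, so they are not technical controls alone. Of all probe sets tested, 29.2% and 25.5% were called in mock and 16.9% and 27% in inoculated plants at 3 and 6 DAI. Chilled and normal arrays thus differed in these probe sets in all 4 comparisons, and chilling and a batch both stay open.

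Inoculation changed fewer probe sets in chilled than in normal plants at 3 DAI (2613 against 3748) and at 6 DAI (2599 against 4359), but with only the arrays of the groups compared this was reversed at 6 DAI (2548 against 1939, and 1438 against 4125 at 3 DAI). The normal comparison at 6 DAI holds replicate 3 of the mock group, which lay nearer to the 3 DAI arrays. Its log2 differences from replicates 1 and 2 had SDs of 0.479 and 0.481, the largest of all replicate pairs. When it was left out of the fit over all arrays, 5797 probe sets were called in normal plants at 6 DAI. Whether it lowered the count of 1939 was not tested. In the fit over all arrays, the variance of each probe set was shared by all groups. Noisier chilled arrays thus could not lower the chilled counts alone. With only the arrays of the groups compared they could, and this was not tested. Over the 1623 probe sets called alike at 6 DAI, the median effect at 3 DAI was 0.569 in chilled and 0.65 in normal plants. The difference was −0.081 (−0.134 to −0.004 with 1 array left out), which compares the size of effects and does not measure noise. Chilled mock leaves that were already shifted toward the inoculated state could contribute, since at 6 DAI the 3748 probe sets called in normal plants at 3 DAI stood a median 0.038 in that direction in chilled mock leaves (0.021 to 0.059). That shift is small beside the median effects, so this explanation stays open.

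Replicate 3 of the mock-inoculated normal plants at 6 DAI lay nearer to the 3 DAI arrays of the same plants than to its own group. An exchange of labels could produce this, as 1 array of the 3 DAI group, replicate 1, correlated better with the other 6 DAI arrays (0.59) than with its own group (0.532). A difference in RNA quality could also contribute, as the array's actin 3' minus 5' value was 3.755, against 4.041 to 4.496 on the other normal arrays, although its ubiquitin value of 1.368 lay within their range (1.216 to 2.334). The lower actin value means relatively more 5' signal, which does not by itself mark poorer RNA. Both explanations stay open, and the labels were kept as given.

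Exchanges of arrays between the groups of a 3 against 3 comparison gave 10 splits each, too few for a share under 0.05. The real grouping gave the most calls, as 1 split of 10, in each of the 8 comparisons. Arrays that changed sides brought the real effect into the spread within groups, so low counts of other splits were largely fixed in advance. The highest count of any other split was 1 in chilled plants at 3 DAI, 1 in chilled plants at 6 DAI, 4 in normal plants at 3 DAI and 979 in normal plants at 6 DAI. It was 4 and 32 for chilled against normal mock plants at 3 and 6 DAI, and 0 and 5 for inoculated plants. The split with 979 calls exchanged replicate 1 of the inoculated group with replicate 3 of the mock group.

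For the interactions 100 splits were drawn. The 258 calls at 3 DAI were reached by 1 split, the real one (highest other 2), and the 10 calls for the change between days in chilled plants also by 1 (highest other 5). Only the main effect was removed, so arrays that changed sides brought any real interaction into the spread within groups. This could lower the counts of the other splits. The low counts are thus weak evidence against chance, and 100 splits do not exclude it. The count of 10 was itself unstable, at 4 to 324 with 1 array left out. The 8 calls of the interaction at 6 DAI were reached by 5 splits (highest other 211), and the 92 calls for the change between days in normal plants by 6 (highest other 2349), so chance could give as many calls. The split with 2349 calls exchanged replicate 1 at 3 DAI with replicate 3 at 6 DAI in the normal mock plants, the arrays named above. It also exchanged replicate 2 at 3 DAI with replicate 2 at 6 DAI in the inoculated normal plants. Its count thus does not show the effect of the mock exchange alone.

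Interactions at 3 DAI in named genes were 3.97 (LOC107946138), 1.56 (Rac9), −2.74 (cdn1), −1.41 (ACO1, LOC107954048), −1.11 (GRPL1/GRPL2/rgp1) and −0.90 (GST, LOC107889738). At 6 DAI they were −2.97 (pod6) and −1.77 (LOC107939902). The change of the inoculation effect between the days in chilled plants was, with mock arrays of pod6 and some arrays of POX5 below the reporter level, −3.20 for pod6, −2.86 for POX5 and −1.77 for LOC107940712. In normal plants, where LOC107947118 lay below the reporter level on 10 of its 12 arrays and E6, FLA13 and POX5 on some of theirs, it was −2.44 for EXPA3D, −2.19 for E6, −2.07 for POX5, −1.93 for LOC107947118, −1.89 for ATub3/TUA6/TubA1, −1.84 for LOC107913168, −1.65 for FLA13 and −1.05 for LOC107940712.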

How the results depend on the processing

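The fit on 22 arrays was chosen only after results were seen, and the other alternatives were fixed before the data were examined.

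With only the arrays of the groups compared, counts moved for inoculated against mock plants (chilled 3 DAI 1438, normal 6 DAI 1939), for chilled against normal mock plants (4315 at 3 DAI, 3580 at 6 DAI) and for the interaction at 6 DAI (17). Asking for 2-fold changes moved the inoculation counts to 704 and 565 in chilled and 912 and 1069 in normal plants at 3 and 6 DAI, the interaction at 3 DAI to 137, the chilled against normal counts to 1003 and 796 in mock and 561 and 1018 in inoculated plants, and the shared calls to 463 and 442. Asking for a mean log2 of at least 5 moved the interactions to 396 and 2 and the list tests to 0 of 24. Only the peroxidase and ethylene lists kept at least 5 genes there, so the NAC and cell wall loosening lists were not tested again. A replicate-number block moved the interaction at 6 DAI to 0 and the change between days in normal plants to 46. A trend with robust variances moved the interaction at 6 DAI to 16 and the change between days in chilled plants to 18. On 22 arrays the interactions moved to 689 and 554 and the changes between days to 25 in chilled and 1157 in normal plants. The cause was not tested.

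With 1 array left out, the inoculation counts ranged over 1503 to 2614 and 1443 to 2235 in chilled and 2357 to 3761 and 2907 to 5797 in normal plants at 3 and 6 DAI. The interactions ranged over 90 to 449 and 0 to 572. Chilled against normal counts ranged over 5177 to 6966 and 4228 to 6164 in mock and 2056 to 3831 and 4459 to 5734 in inoculated plants. The changes between days ranged over 4 to 324 in chilled and 14 to 1119 in normal plants, shared calls over 973 to 1414 and 1044 to 2182, and list tests past the threshold over 10 to 16, against 13.

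Replicate numbers did not pair across groups: in 0 of 8 comparisons were all correlations of like numbers above 0.1. The block made 8 of the 289 calls in named genes weaker and no call stronger.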

Other observations

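The lists of tubulins, fasciclin-like proteins and other groups in this part were composed only after results were seen.

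Of 6 tubulins, 4 were lower in inoculated chilled plants at 6 DAI, 3 in normal plants at 6 DAI and 2 in chilled plants at 3 DAI, while in normal plants at 3 DAI 1 was higher. ATub3/TUA6/TubA1 (LOC107886968) fell by 1.71 in normal plants at 6 DAI (adjusted p = 0.00013) and by 0.94 in chilled plants (0.03). The camera test gave adjusted p = 0.0064, 0.017 and 0.014 for the first 3 comparisons, each lost in the second form of the test (adjusted p = 0.78 with an estimated correlation). The tubulins also shifted in the interaction at 3 DAI (0.017) and in the change between days in normal plants (0.0064), both again at 0.78 with an estimated correlation. In that change the fasciclin-like list passed as well (0.017, and 0.83 with an estimated correlation). FLA13 (LOC107911922) of the 12 fasciclin-like genes was higher in inoculated normal and chilled plants at 3 DAI (adjusted p = 0.00012 and 0.0044), with 3 and 1 of the 3 mock arrays below the reporter level. The lists of antioxidant, fatty acid, kinase and calcium, and seed genes did not pass in any comparison.

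The smaller cdn1 and GST responses of chilled leaves at 3 DAI may come from a raised level before inoculation, since both genes stood higher in chilled mock leaves, but the wider shift of mock leaves toward the inoculated state, 0.038, was measured at 6 DAI and does not speak for 3 DAI. Mock and inoculated leaves sampled at the end of chilling and through the days before 3 DAI, measured by quantitative PCR, would test this.

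The higher CHS6 and DFR and lower SusA1 and CSD2a/CSD2b of chilled leaves could reflect chilling, a processing batch, RNA quality or several of these. The reporter probe sets differed beyond chance in mock plants at 3 DAI (exact p = 0.0079) and not past the threshold in the other comparisons (0.12, 0.75 and 0.059). The array maker's control probe sets, like CHS6, SusA1 and CSD2a/CSD2b, differed in all 4 comparisons, with 44, 49, 41 and 45 of 103 called. They include probe sets for cotton's own actin and ubiquitin. For inoculation, 6 of 103 were called in normal plants on each day and 0 in chilled plants. The actin and ubiquitin 3' minus 5' values also differed between chilled and normal arrays (−0.543 and −0.502, permutation p = 5e-05 and 0.0049). Samples of both kinds of plant, processed in mixed order with the same amount of control transcripts, would separate these.

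Whether the peroxidase response of chilled plants was shorter stays open. The splits, 1 of 100 with as many calls, were weak evidence against chance for the count of changes between the days and did not test any gene. The pod6 call was lost in 8 of 12 fits that left out 1 array, and its mock arrays and 2 of 3 inoculated arrays at 6 DAI lay below the reporter level. The POX5 call in chilled plants (−2.86) was kept in all 12, although some of its arrays also lay below that level. pod7 was still 6.52-fold higher at 6 DAI in chilled plants, and the effect on POX5 was smaller at 6 DAI in normal plants too (−2.07). Peroxidase activity and fungal biomass measured daily in both kinds of plant would test it.

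The count of changes between the days in normal plants, EXPA3D and E6 among them, might be held down by replicate 3 of the mock group at 6 DAI, since 1119 probe sets were called without it, but this fit was singled out after its array was seen to lie apart. New mock leaves sampled on both days would settle it.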
